A study of Mus musculus with 8 samples.

How the data were processed

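The series holds RNA sequencing of endothelial cells sorted by flow cytometry from whole mouse embryos at embryonic day 15.5. Pregnant females either received tamoxifen by gavage at embryonic day 12.5 or did not. Per the labels, the mice carry a tamoxifen-inducible Cre recombinase driven by the endothelial gene Cdh5 and a Cre-dependent reporter at the Rosa26 locus, while the genotype field of each sample says wild type. Tamoxifen and any activation of the recombinase by it were therefore not separated by any group, and recombination itself was not measured here. The labels list 8 samples, 4 per group. They do not say whether the samples came from separate litters or embryos, so p-values measure only the spread between these samples, which may be technical. Libraries were made from ribosomal-RNA-depleted RNA and, per the labels' protocols, were processed at the same time. Whether counting used the strand of the reads is not given in the sources used here.

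The deposited values are a signal unit, normalised read counts per gene symbol in 1 table of 23337 genes. The submitters' processing notes name STAR, HTSeq 0.11.2 and DESeq2, and list the builds hg38 and mm10, without giving their roles. In every column used, 100% of the deposited values were whole multiples of 1 step, within a tolerance of 0.001 reads, so whole reads could be recovered. The recovered reads gave the depth of each library and were used for count tests as alternatives. A gene-level value of 0 was read as no counted read.

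The header of the table has 9 fields, including 8 library names, while each data line has 10 fields, including 9 values. The names can be placed over the last 8 value columns, as R does with a short header, or over the first 8. Columns 3 to 5 carry a name without tamoxifen and columns 7 to 9 a name with tamoxifen under both placements. The main comparison used these 6 libraries, 3 per group, called no_tamoxifen_1 to no_tamoxifen_3 and tamoxifen_1 to tamoxifen_3 in table order. The design fixed before the data were examined had all 8 named libraries, and this departure follows from the header. Column 6 was already known to be unlike the other columns when it was decided, but no test between groups had been run. A name missing from inside a group is not excluded by the table. Column 6 belongs to the group without tamoxifen in the first placement and to the tamoxifen group in the second, and column 10 is a tamoxifen library in the first and has no name in the second. Both entered only alternatives added after the header was seen. The 1 remaining value column, the first, was not used. The second placement names it as a library without tamoxifen, so the alternative for that placement had 3 libraries against 4 and is not the whole of that reading.

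Genes with a mean of at least 10 normalised reads over the 6 libraries were tested, 13480 in all. The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with empirical Bayes moderation and a mean-variance trend, group as the only term, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2(value + 1) scale, which understates the change of low genes. The 33 gene lists and 14 marker lists were fixed before the data were examined. Of their 911 symbols, 894 were found in the table, and 43 lists had the 4 tested members required. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 43 lists together, and again with an estimated correlation and with fry. A list score is the mean of log2(value + 1) over its tested members in a library. Scores were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

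The named genes were to be those past the threshold with a mean of at least 50 and no overlap between groups, without predicted or clone-named genes. Since under 10 genes passed, the rule's provision for that case applied: the 10 genes of lowest p in each direction are named, and are given as not past the threshold where that holds. 1 of these genes is not reported here. Members of lists were taken by lowest p, and 4 check genes were named whatever their values. Coordinates are 1-based on GRCm38, the assembly also called mm10, from GENCODE M21.

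The tests were checked on simulated counts for the same 13480 genes and the 3 against 3 comparison, with 200 changed genes in each of 5 simulations. limma recovered 56.8% of genes changed 2-fold, 82.4% at 4-fold and 98.8% at 8-fold, and 6.3% of its calls were false. DESeq2 recovered 65.6%, 88.8% and 99.6%, with 16.5% of its calls false. camera found the shifted list in 5 of 5 simulations. The simulated genes varied independently, with no variation shared across genes between libraries. In the data the first principal component held 61.1% of the variance. The rates for limma and DESeq2 therefore need not hold here, and camera was not checked on lists whose members vary together. In the data the estimated correlation was 0.935 for the mesenchymal and fibroblast list and 0.914 for the cartilage list.

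Alternatives were other pseudocounts, filters, scalings, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and each library left out in turn. Those added after the data were seen were both placements of the header, column 10 added, tamoxifen_3 as the only tamoxifen library with or without column 10, and a mesenchymal marker score as a covariate. With tamoxifen_3 as the only tamoxifen library, no spread among tamoxifen libraries enters a p value. Calls in that setting describe that library and not the treatment. The covariate also leans on tamoxifen_3, since the score was 9.23 and 9.74 in tamoxifen_1 and tamoxifen_2 against 5.76 in it. In alternatives camera kept the preset correlation unless stated. A list of heat shock factor targets was also written after the most changed genes had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the table and the plots.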

Results

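Transcriptomes of endothelial cells sorted from E15.5 mouse embryos were compared between 3 libraries without tamoxifen and 3 from embryos whose mothers received tamoxifen at E12.5. The comparison asks which transcripts differ in cells sorted as endothelial after tamoxifen, the drug that activates inducible Cre recombinases. Myeloid transcripts were abundant in these sorts, with the macrophage receptor gene Csf1r at 7464 to 12229 normalised reads and the endothelial Cdh5 at 1978 to 5201. A change in these libraries therefore cannot be assigned to endothelial cells. The 6 libraries held 12212472 to 19908404 reads in genes and 16548 to 17253 genes above 0. The ribosomal RNA precursor Rn45s took 29.4% to 38.7% of those reads, which left 8436939 to 13283464 reads for other genes. Values are the authors' normalised read counts.

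Chaperone genes of the heat shock response had the lowest p values. Hspa1b, which encodes a stress-inducible cytosolic chaperone, rose from 1412 ± 282 normalised reads without tamoxifen to 57355 ± 18427 with it (SD, n = 3 each), a 39.9-fold increase with a 95% interval of 27.6 to 57.7. Its near-identical neighbour Hspa1a rose from 1137 ± 140 to 32468 ± 11569 (SD, n = 3 each), 27.6-fold. The co-chaperone Dnajb1 rose 8.46-fold and the nucleotide exchange factor Hsph1 8.63-fold. The chaperone regulator Bag3 rose from 335 ± 53 to 1379 ± 476 (SD, n = 3 each). The immediate early gene Nr4a1, which encodes an orphan nuclear receptor, rose 2.31-fold, from 3477 ± 439 to 7987 ± 406 (SD, n = 3 each).

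**Figure D1:**
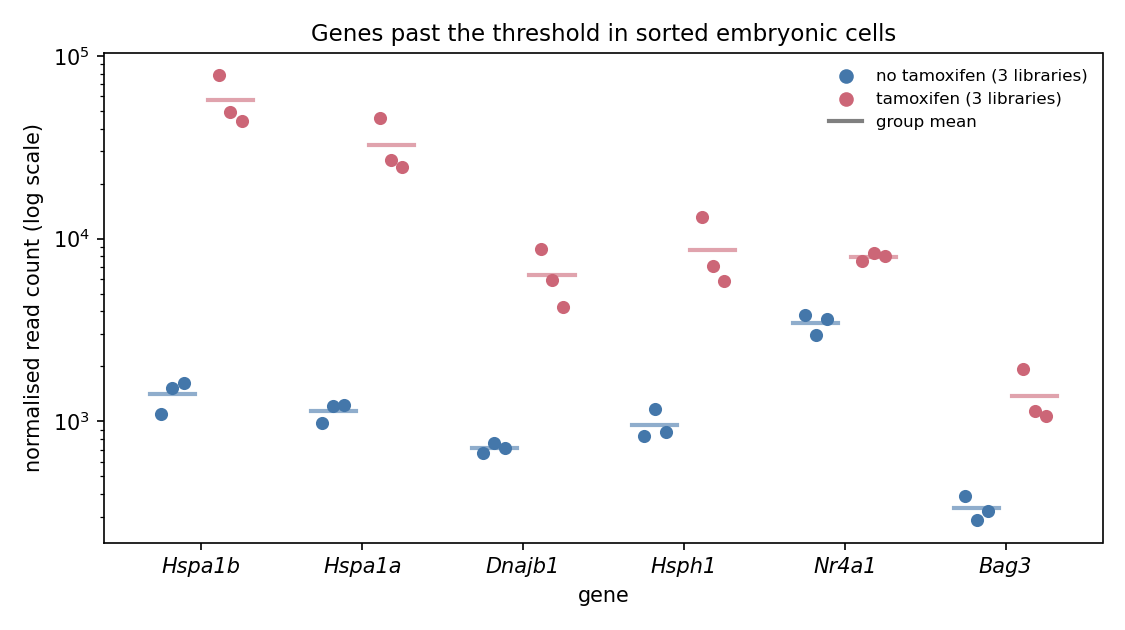
Normalised read counts, on a log axis, of the 6 genes past the threshold in each library, with points for the 3 libraries per group and a bar for the group mean. For each gene all 3 tamoxifen libraries lie above all 3 libraries without tamoxifen, with Hspa1b at a mean of 57355 against 1412.

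In limma with Benjamini-Hochberg adjustment the log2 fold changes were 5.32 ± 0.23 (SE) for Hspa1b and 4.79 ± 0.22 for Hspa1a, each with an adjusted p of 8.83e-05. They were 3.08 ± 0.23 for Dnajb1 (limma adjusted p = 0.0027) and 3.11 ± 0.28 for Hsph1 (limma adjusted p = 0.00808). They were 1.21 ± 0.12 for Nr4a1 (limma adjusted p = 0.0158) and 2.00 ± 0.23 for Bag3 (limma adjusted p = 0.0362). Hspa1b lies on chromosome 17 at 34956436 to 34959238 and Hspa1a at 34969190 to 34972156, both on the minus strand of GRCm38. How reads were divided between these paralogs is uncertain, and Hspa1a also overlaps the annotated gene Gm20481. Dnajb1 lies on chromosome 8 at 83608193 to 83612653, Hsph1 on chromosome 5 at 149614287 to 149636376 and Nr4a1 on chromosome 15 at 101254269 to 101274795. Bag3, on chromosome 7 at 128523616 to 128546981, overlaps the annotated gene 2610306O10Rik.

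These 6 genes were the calls of the limma test among 13480 genes, 6 higher and 0 lower. At an unadjusted p under 0.05, 659 genes were higher and 556 lower, where 674 are expected by chance in total. edgeR with TMM on recovered reads called 5 higher and 0 lower, and DESeq2 called 247 higher and 28 lower. The groups did not overlap for 13.9% of genes, where chance gives 10%. With the header names placed over the first 8 value columns, which puts column 6 in the tamoxifen group, and with the unused column, named there as without tamoxifen, left out, no gene passed. In that setting Hspa1b was at 3.84 ± 1.49 (SE, limma adjusted p = 0.718) and Hspa1a at 3.29 ± 1.51, with 924 and 488 normalised reads in column 6. With the names over the last 8 the calls were Hspa1a, Hspa1b, Dnajb1 and Hsph1, without Nr4a1 and Bag3 (limma adjusted p = 0.127 each). Without tamoxifen_3 the limma count was 973 higher and 469 lower, and without no_tamoxifen_1, no_tamoxifen_2 or no_tamoxifen_3 it was 3, 2 and 2 higher, with Hspa1a and Hspa1b among the calls each time. Without tamoxifen_1 or tamoxifen_2 it was 5 and 4 higher. Nr4a1 passed only in the leave-out of tamoxifen_3, with limma adjusted p values of 0.0791 to 0.155 in the other 5. Bag3 passed only without tamoxifen_1 or tamoxifen_3 (limma adjusted p = 0.0853 to 0.410 in the other 4) and did not pass in edgeR with TMM (adjusted p = 0.0528). Hsph1 was lost without each library lacking tamoxifen (limma adjusted p = 0.0791 to 0.155), and Dnajb1 without no_tamoxifen_2 or no_tamoxifen_3 (limma adjusted p = 0.0696 and 0.0795).

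Among lists, the dissociation and immediate early genes were higher with tamoxifen, with 15 of 19 tested members positive and a median log2 fold change of 0.34. Of the 19, 5 rose over all genes and 8 rose adjusted over the list alone. The 5 are Hspa1b, Hspa1a, Dnajb1, Hsph1 and Nr4a1, so 4 of them are heat shock genes rather than immediate early genes. The transcription factor Jun passed over the list alone at 0.61 ± 0.13 (SE). The list's score was 11.44 to 11.63 without tamoxifen and 12.58 to 12.64 with it. Its camera adjusted p was 5.69e-13 with the preset correlation and its adjusted p was 0.659 with an estimated correlation. Much of that score difference comes from the 4 heat shock genes. The 15 other members had a median log2 fold change of 0.288 (camera p = 1.12e-05 with the preset correlation, and p = 0.215 with an estimated correlation). In the same libraries the Y-linked score was 7.64 to 7.96 with tamoxifen and 4.74 to 7.15 without it, and the mesenchymal score was above every library without tamoxifen by over 3 in 2 of 3 tamoxifen libraries. The unfolded protein and integrated stress response list, which covers stress of the endoplasmic reticulum, had a median of -0.04 over 22 members. It was not called (camera adjusted p = 0.593), though it was called lower without tamoxifen_3 (camera adjusted p = 0.0359). Its score in tamoxifen_3, 9.63, lay above the 9.37 to 9.49 without tamoxifen.

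Markers of connective tissue separated 2 of the tamoxifen libraries from the rest. The mesenchymal and fibroblast score was 9.23 in tamoxifen_1 and 9.74 in tamoxifen_2, against 5.76 in tamoxifen_3 and 4.64 to 5.92 without tamoxifen. All 13 tested members were positive, with a median log2 fold change of 2.94. No member passed over all genes and 12 passed adjusted over the list alone, among them the matrix genes Postn (3.30 ± 0.84, SE) and Col1a1 (3.38 ± 0.97) and the growth regulator Dlk1 (2.67 ± 0.72). Cartilage markers followed the same libraries, at 9.41 and 9.06 against 5.46 in tamoxifen_3 and 5.18 to 5.35 without tamoxifen. Of 10 tested cartilage genes 0 passed over all genes and 8 adjusted over the list alone, including Acan (4.10 ± 1.20), the core protein of cartilage proteoglycan. Mural cell markers had a median of 1.38 over 9 members, with 0 past either threshold, and Pdgfrb at 0.53 ± 0.15. The camera adjusted p values were 6.69e-12, 2.70e-08 and 0.000937, and all 3 lists had an adjusted p of 0.659 with an estimated correlation. With the header names over the last 8 value columns none of the 3 was called (camera adjusted p = 0.294, 0.561 and 0.358). With tamoxifen_3 as the only tamoxifen library the cartilage and mural lists were not called. The mural score of tamoxifen_3, 4.64, lay below the 4.97 to 5.93 without tamoxifen. With the mesenchymal score as a covariate the mural list was called lower (camera adjusted p = 0.00251). The exact permutation p of the scores was 0.2 for mesenchymal, 0.1 for cartilage and 0.4 for mural markers, and 0.723, 0.470 and 0.752 after adjustment over 47 scores.

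**Figure D2:**
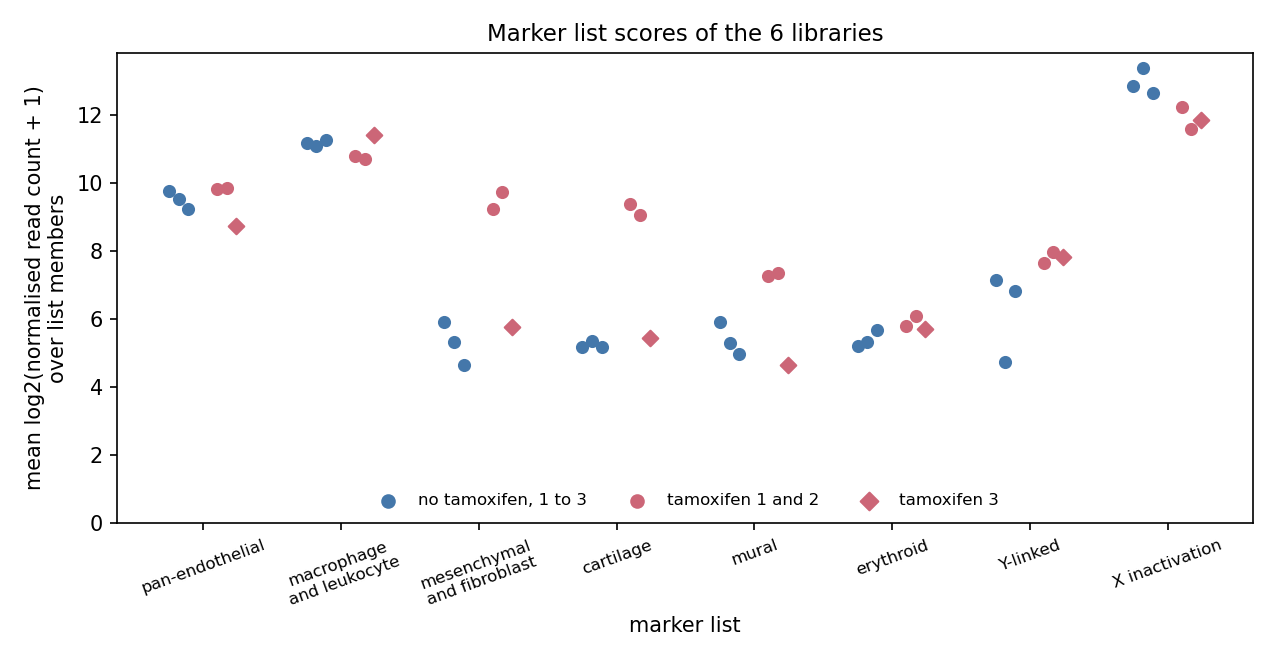
Scores of 8 lists, as the mean log2(normalised read count + 1) over members, with one point per library, blue without tamoxifen and red with it, and tamoxifen_3 as a diamond. The mesenchymal score is 9.23 and 9.74 in tamoxifen_1 and tamoxifen_2 and 5.76 in tamoxifen_3.

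The direction of endothelial identity genes depended on the libraries used. The pan-endothelial list had 14 positive and 15 negative members and a median of -0.02 and was not called (camera adjusted p = 0.995), and its score was 9.85 and 9.88 in tamoxifen_1 and tamoxifen_2 and 8.76 in tamoxifen_3. It was called higher without tamoxifen_3 (camera adjusted p = 9.52e-06). It was called lower in the planned leave-out of tamoxifen_2 (camera adjusted p = 0.0442). It was also called lower with column 10 added (camera adjusted p = 0.0206), a setting added later. The same held with the header names over the first 8 value columns (camera adjusted p = 0.0164). With the mesenchymal score as a covariate, a fit that leans on tamoxifen_3, it was called lower as well (camera adjusted p = 8.66e-30). These calls used the preset correlation of 0.01, while the list's estimate in the main comparison was 0.649. In tamoxifen_3 its score of 8.76 lay below the 9.25 to 9.76 without tamoxifen. Tip cell, venous, lymphatic, brain endothelial and barrier, lung endothelial and liver sinusoidal lists were not called in the main comparison. The lymphatic list was called lower with the replicate number as a block and with column 10 added (camera adjusted p = 0.0335 and 0.0333). With the header names over the last 8 value columns the brain list was called lower and the liver sinusoidal list higher (camera adjusted p = 6.93e-05 and 0.00694). All 6 were called lower with the mesenchymal score as a covariate, a fit that leans on tamoxifen_3. Without tamoxifen_3 the tip cell, brain, lung and liver sinusoidal lists were called higher (camera adjusted p = 2.01e-05, 0.00391, 0.000412 and 0.00141). Each of the 6 scores was lower in tamoxifen_3 than in every library without tamoxifen. For the brain list it was 6.73 against 7.52 to 8.13, and for the liver sinusoidal list 7.39 against 7.67 to 7.94. In other leave-outs the brain list was called lower without tamoxifen_1 or tamoxifen_2 (camera adjusted p = 0.0448 and 0.0486), the lymphatic list lower without tamoxifen_2 (camera adjusted p = 0.0159) and the tip cell list higher without no_tamoxifen_1 (camera adjusted p = 0.0131). The arterial list was called higher, with 17 of 18 members positive and a median of 0.34 (camera adjusted p = 0.000436, and adjusted p = 0.824 with an estimated correlation). No arterial gene passed over all genes, while the gap junction gene Gja5 (1.94 ± 0.42, SE) and the elastic fibre gene Fbln5 (1.68 ± 0.34) passed adjusted over the list alone. Endocardial genes had a median of 0.88 over 8 members (camera adjusted p = 0.00681, and adjusted p = 0.659 with an estimated correlation). Endothelial-to-mesenchymal transition genes had a median of 0.43 over 13 (camera adjusted p = 0.0157, and adjusted p = 0.824 with an estimated correlation). Neither list had a member past a threshold over all genes or over the list alone. The largest values in the latter were Col1a1 and Twist1 (2.52 ± 0.79). In tamoxifen_3 both the arterial and transition lists went in the opposite direction. Their scores there, 7.30 and 6.76, lay below every library without tamoxifen (7.36 to 7.84 and 6.83 to 7.38). The transition list was not called without no_tamoxifen_3, tamoxifen_1 or tamoxifen_2 (camera adjusted p = 0.231, 0.159 and 0.166), nor the endocardial list without tamoxifen_2 (camera adjusted p = 0.0524). None of the arterial, endocardial and transition lists was called with the header names over the last 8 value columns (camera adjusted p = 0.332, 0.994 and 0.455) or with column 10 added (camera adjusted p = 0.328, 0.0846 and 0.307).

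Blood cell and sex markers also differed in places. All 17 macrophage and leukocyte genes were negative, with a median of -0.21 (camera adjusted p = 0.00893, and adjusted p = 0.824 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The list was not called without no_tamoxifen_3, tamoxifen_1 or tamoxifen_2 (camera adjusted p = 0.147, 0.150 and 0.298). That score was 10.79 and 10.72 in tamoxifen_1 and tamoxifen_2, 11.42 in tamoxifen_3 and 11.10 to 11.28 without tamoxifen, so tamoxifen_3 lay above every library without tamoxifen. Erythroid, megakaryocyte and platelet, hepatocyte, epithelial and neural lists were not called, though neural genes were called higher without tamoxifen_3 (camera adjusted p = 0.0462). The epithelial score of tamoxifen_3, 2.95, lay below the 3.84 to 5.33 without tamoxifen. The 4 Y-linked genes were higher, 0 over all genes and 4 adjusted over the list alone, from Eif2s3y at 1.86 ± 0.62 (SE) to Uty at 1.35 ± 0.51. The Y-linked score was 7.15, 4.74 and 6.83 without tamoxifen and 7.64, 7.96 and 7.84 with it (camera adjusted p = 0.000527, and adjusted p = 0.659 with an estimated correlation). The X inactivation score, from Xist and Tsix, was 12.65 to 13.40 without tamoxifen and 11.61 to 12.25 with it (exact permutation p = 0.1, adjusted p = 0.470).

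Signalling lists had few members past a threshold. In the NF-kB and leukocyte adhesion list, 14 of 17 members were positive, and the cytokine genes Il6 (1.01 ± 0.21, SE) and Csf1 (0.56 ± 0.15) passed adjusted over the list alone. In the p53 and DNA damage response list 3 of 22 passed in that way, Plk3 (0.71 ± 0.15), Eda2r (2.98 ± 0.71) and the antiproliferative gene Btg2 (0.38 ± 0.09). In the estrogen responsive list 1 of 23 did, Hspb1 (3.32 ± 0.58), which encodes a small heat shock protein. The BMP and TGF-beta list had a median of 0.33 over 14 members. Its score was 7.98 and 8.09 in tamoxifen_1 and tamoxifen_2, 7.28 in tamoxifen_3 and 7.21 to 7.44 without tamoxifen. No member of these 4 lists passed over all genes. The camera adjusted p values of these 4 lists were 0.00147, 0.0157, 0.0233 and 0.0118, and each list had an adjusted p of 0.659 with an estimated correlation. Without tamoxifen_3 the NF-kB, p53 and estrogen lists were not called (camera adjusted p = 0.122, 0.414 and 0.182). The p53, estrogen and BMP and TGF-beta lists were not called without no_tamoxifen_3 (camera adjusted p = 0.168, 0.0800 and 0.0997), nor the last of them without tamoxifen_2 (camera adjusted p = 0.0777). Estrogen and BMP and TGF-beta lists were not called with the header names over the last 8 value columns (camera adjusted p = 0.155 and 0.935) or with column 10 added (camera adjusted p = 0.0671 and 0.584), nor NF-kB and estrogen lists with the names over the first 8 (camera adjusted p = 0.904 and 0.0933). The shear stress list was called higher without a member past a threshold (camera adjusted p = 0.0241, and adjusted p = 0.659 with an estimated correlation). Its score was 9.34 and 9.50 in tamoxifen_1 and tamoxifen_2, 8.87 in tamoxifen_3 and 8.92 to 9.12 without tamoxifen. It was not called without no_tamoxifen_2, no_tamoxifen_3 or tamoxifen_2 (camera adjusted p = 0.0732, 0.117 and 0.344). Nor was it called with the names over the last 8, with column 10 added or with the names over the first 8 (camera adjusted p = 0.609, 0.451 and 0.216). The cholesterol synthesis and uptake list, whose late steps tamoxifen can inhibit, had a median of -0.06 over 26 members and was not called (camera adjusted p = 0.426), though it was called lower with the names over the last 8 (camera adjusted p = 0.0298). Interferon response, hypoxia and glycolysis, Notch target and xenobiotic response lists were not called. The interferon score was 7.17, 6.30 and 7.68 in the 3 tamoxifen libraries and 7.03 to 7.11 without tamoxifen. That list was called higher without tamoxifen_2 and with the names over the last 8 (camera adjusted p = 6.87e-05 and 0.000117). It was called lower without tamoxifen_3 and with the names over the first 8 (camera adjusted p = 0.00806 and 0.0164). Notch targets were called higher without tamoxifen_3 and lower with that library alone (camera adjusted p = 0.000549 and 0.0395), and hypoxia genes higher with it alone (camera adjusted p = 0.0439).

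Growth and metabolism lists moved by small amounts. Replication-dependent histones had 41 of 61 members negative and a median of -0.10, with Hist1h1c at -0.68 ± 0.16 (SE). Nuclear oxidative phosphorylation genes had 18 of 20 negative and a median of -0.18, G2/M genes 18 of 20 negative and a median of -0.10, and lysosome genes 18 of 22 negative and a median of -0.16. G1/S genes had 17 of 20 positive and a median of 0.13. None of these 5 lists had a member past the threshold over all genes or over the list alone. Their camera adjusted p values were 0.000527, 0.00264, 0.0157, 0.0349 and 0.0259, and their adjusted p values with an estimated correlation were 0.824, 0.659, 0.659, 0.849 and 0.824. Histones and G2/M genes were not called without no_tamoxifen_3 (camera adjusted p = 0.503 and 0.195), G1/S and G2/M genes without tamoxifen_3 (camera adjusted p = 0.747 and 0.0980), G1/S genes without no_tamoxifen_1 (camera adjusted p = 0.371) and histones without tamoxifen_2 (camera adjusted p = 0.0742). With 1 library left out, lysosome genes were called only without no_tamoxifen_2 or tamoxifen_3 (camera adjusted p = 0.0263 and 3.51e-05). Quantile normalisation ended the G2/M and lysosome calls (camera adjusted p = 0.148 and 0.0920). The names over the first 8 ended those of histones, G2/M and G1/S genes (camera adjusted p = 0.0851, 0.836 and 0.0531), and the names over the last 8 those of oxidative phosphorylation and lysosome genes (camera adjusted p = 0.132 and 0.0843). With column 10 added lysosome genes were not called (camera adjusted p = 0.0671), and with tamoxifen_3 alone histones, oxidative phosphorylation and G2/M genes were not (camera adjusted p = 0.114, 0.660 and 0.0538). Cytosolic ribosomal proteins had a median of -0.05 over 75 members and were not called (camera adjusted p = 0.316). They were called lower without no_tamoxifen_1 and with the header names over the first 8 value columns (camera adjusted p = 0.0130 and 2.92e-06), and higher with the names over the last 8 (camera adjusted p = 5.93e-08). Over all lists, camera with the preset correlation called 14 higher and 5 lower of 43, and 0 with an estimated correlation or with fry.

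Other genes of lowest p did not pass the threshold in the main comparison. Among those with higher values, Wdr95 had 8.24 ± 2.65 normalised reads without tamoxifen and 95.2 ± 49.8 with it (SD, n = 3 each, limma adjusted p = 0.0924). It lies on chromosome 5 at 149528679 to 149611894, next to Hsph1, and overlaps Gm15997. The co-chaperone gene Dnaja1 (1.06 ± 0.15, SE, limma adjusted p = 0.099) and the nuclear receptor gene Nr4a3 (1.06 ± 0.16, limma adjusted p = 0.149) followed. Dnaja1 overlaps Smu1. Among those with lower values, Gatm, which encodes the first enzyme of creatine synthesis, had 2319 ± 292 reads without tamoxifen and 1302 ± 23 with it (SD, n = 3 each, limma adjusted p = 0.099). The nuclear RNA Neat1 (-0.92 ± 0.16, SE) and the phagocyte receptor gene Timd4 (-0.97 ± 0.17) each had a limma adjusted p of 0.227. Tsix, whose reads cannot be told apart from those of the overlapping Xist without strand, was at -1.11 ± 0.21. Ccl6, H2-T23, Kpna2, Abcb1b, Clec7a and Rilpl2 completed the list, with limma adjusted p values from 0.315 to 0.369. Their values ranged from -1.17 ± 0.26 for Abcb1b to -0.52 ± 0.11 for Kpna2.

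Genes tied to the transgenes did not pass the test. Rpl10a, the ribosomal protein carried by the reporter, had 4188 ± 590 normalised reads without tamoxifen and 4854 ± 652 with it (SD, n = 3 each, limma adjusted p = 0.665). Esr1 was checked because the inducible recombinase holds an oestrogen receptor domain, whose reads may not be counted under that gene. It had 10.01 ± 2.72 and 13.1 ± 1.80 reads (SD, n = 3 each, limma adjusted p = 0.824). These values are near the minimum mean of 10, so they say little about the transgene. Cdh5 had 4084 ± 1050 and 3986 ± 1751 (SD, n = 3 each, limma adjusted p = 0.936), and Gt(ROSA)26Sor, which overlaps Thumpd3, had 61.5 ± 10.5 and 72.0 ± 5.9 (SD, n = 3 each, limma adjusted p = 0.772). With the mesenchymal score as a covariate Cdh5 passed at -1.21 (limma adjusted p = 8.20e-05). That fit leans on tamoxifen_3, where Cdh5 had 1978 reads. The score was 5.76 there, against 9.23 and 9.74 in tamoxifen_1 and tamoxifen_2. In no_tamoxifen_1 to no_tamoxifen_3 the score, 5.92, 5.34 and 4.64, fell in the same order as Cdh5, at 5020, 4282 and 2948. The covariate therefore cannot separate other cell types from endothelial content.

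The axis along which the libraries differed most did not separate the groups, and whether treatment contributed to it was not tested. The first principal component held 61.1% of the variance and placed tamoxifen_1 at 51.8 and tamoxifen_2 at 57.3, with tamoxifen_3 at -33.8 and the libraries without tamoxifen between -33.9 and -15.1. Spearman correlations across genes, which are not independent replicates, were 0.986 to 0.991 among libraries without tamoxifen, 0.953 to 0.990 among tamoxifen libraries and 0.958 to 0.990 between groups. Within each group no library was a repeat of another, since counts differed by 7.6 to 50.6 chi-square units per degree of freedom.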

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

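The tests of other cell types and of shared reads and of embryo sex for the heat shock genes, and of the endothelial score of column 6, were chosen after the results were seen. Columns 6 and 10, outside the main comparison, held signals above the libraries without tamoxifen. In column 10 the normalised counts of the called genes were 56354 for Hspa1b, 32334 for Hspa1a, 5231 for Dnajb1, 9181 for Hsph1, 7470 for Nr4a1 and 1148 for Bag3. Column 6 exceeded the highest library without tamoxifen by 6.49 log2 units in the cartilage score, 5.79 in the mesenchymal and fibroblast score, 5.15 in the erythroid score and 3.19 in the mural score.

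Heat shock genes were higher in the tamoxifen libraries. Reads shared between Hspa1a and Hspa1b are argued against as the whole cause. The other 29 heat shock factor targets had a median log2 fold change of 0.576, with 27 positive. Their list was written after the most changed genes had been seen and includes the called Dnajb1, Hsph1 and Bag3. How reads were divided between Hspa1a and Hspa1b was not tested. Embryo sex is argued against as the whole cause, since the heat shock score ranged over 0.13 without tamoxifen, against a difference of 1.18 between groups, while the Y-linked score ranged over 2.41, against 1.57. For other cell types in 2 of the tamoxifen libraries, the prediction as written does not decide. In tamoxifen_3, low in mesenchymal markers, the heat shock score was 0.88 above the highest library without tamoxifen, between the bounds set. A criterion outside that prediction was added: all 5 called heat shock genes passed with the mesenchymal score as a covariate (Hspa1b 5.12 ± 0.25, SE). That fit leans on tamoxifen_3. Column 6, whose group is not fixed, had the highest mesenchymal score and a heat shock score of 9.36 against at most 9.45 without tamoxifen. Other cell types are still argued against as the whole cause, since tamoxifen_3 had 44218 normalised reads of Hspa1b against 1091 to 1618 without tamoxifen. Stress during dissociation and sorting may account for the pattern, but its test does not decide. The 15 immediate early members without heat shock genes, Nr4a1 among them, had a median of 0.288, under the bound set for it. The prediction was met only by camera with the preset correlation (camera p = 1.12e-05, and p = 0.215 with an estimated correlation). With the preset correlation camera also called 7 to 31 lists in each other split of the 6 libraries into 3 and 3. Such stress cannot be separated here from tamoxifen or recombinase activation, which stay open.

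For the number of genes, 1 of the 10 splits of the 6 libraries gave at least 6, the real one, and the highest other gave 1. For the number of lists, 4 of the 10 splits gave at least 19, and the highest other gave 31, in the split that sets no_tamoxifen_1, tamoxifen_1 and tamoxifen_2 against the rest. With 10 splits a share under 0.05 cannot be reached.

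Mesenchymal markers were higher in 2 of the tamoxifen libraries. If more cells of other types entered those 2 sorts, 5 other lists should be higher in both than in tamoxifen_3, and 4 were (mural, cartilage, epithelial and neural). The exception, skeletal muscle, rests on 2 tested genes, at 4.66 and 4.10 against 4.23, and the epithelial scores of 4.46 and 5.01 lie inside the range of 3.84 to 5.33 without tamoxifen, so that list counts only because tamoxifen_3 is low at 2.95. The leukocyte score was lower in both, so markers of other types did not all move alike. What keeps this open is the small number of libraries and genes, and a change in tissue composition with treatment was not tested.

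Column 6 stood apart, with Spearman correlations of 0.659 to 0.759 with the 6 libraries. Low depth is argued against, since the 6 libraries thinned to its reads kept correlations of at least 0.952. Its pan-endothelial score was -0.43 relative to the lowest other library, column 10, inside the bound of 1 set against a library of mainly other cells. That bound was wrong, because column 10 is itself low and column 6 lay -1.15 from the lowest of the 6. In 4 of 11 marker lists column 6 lay over 2 above the highest other library, as such a library would show, so this stays open. No explanation from treatment was tested, since the header does not fix its group.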

How the results depend on the processing

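Alternatives using either placement of the header, column 10, tamoxifen_3 alone or the mesenchymal covariate were chosen after the data were seen. No called gene changed direction in any alternative run for it. Of 96 checks on the 6 called genes, 73 stayed past the threshold, and Hspa1b and Hspa1a lost it only with the header names over the first 8 value columns, the unused one left out (log2 fold changes 3.84 and 3.29, limma adjusted p = 0.718), where 0 genes were higher. The counts of higher and lower genes were 460 and 228 with array weights, and 247 and 28 with DESeq2 on recovered reads. Of the 275 DESeq2 calls, 268 were also called without tamoxifen_3. Of the higher and lower DESeq2 calls, 34.4% and 0% had a tamoxifen_3 value not beyond the libraries without tamoxifen. For calls made without tamoxifen_3 the shares were 73.8% and 68.7%. The DESeq2 fit included tamoxifen_3, which disfavours genes where that library lies among the others. The difference in shares is therefore partly fixed by selection and tests no cause. Adding column 10 gave 1 lower gene. The counts were 28 and 63 with tamoxifen_3 as the only tamoxifen library, assumed to vary like the others, 143 and 443 with tamoxifen_3 and column 10, and 137 and 499 with the mesenchymal covariate. In the last 2 settings 1 of the reporter and receptor checks, Cdh5, passed. The cause of the differing counts was not tested. Leaving out each library in turn gave 2 to 973 higher genes, 0 to 469 lower genes, 6 to 18 gene lists and 5 to 7 marker lists. Called gene lists numbered 0 with an estimated correlation, where called marker lists were also 0, and 0 with fry. They numbered 22 with tamoxifen_3 alone, 24 with tamoxifen_3 and column 10, and 22 with the covariate. The first component held 75.9% of variance over the 1000 most variable genes.

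Lists called in the main comparison reversed direction in 30 instances, with the camera adjusted p values given here. With tamoxifen_3 alone they were 0.000278 for arterial, 0.763 for BMP and TGF-beta, 0.0395 for endothelial-to-mesenchymal transition, 0.0108 for lysosome, 0.000553 for leukocyte, 0.0788 for mural, 0.114 for histone and 0.331 for shear stress lists. With tamoxifen_3 and column 10 they were 7.71e-08 for arterial, 0.0151 for BMP and TGF-beta, 0.515 for endocardial, 0.00557 for transition, 0.177 for lysosome, 0.260 for leukocyte, 0.0592 for mural and 0.0183 for shear stress lists. With the covariate they were 5.71e-07 for arterial, 0.548 for BMP and TGF-beta, 0.718 for endocardial, 0.00341 for transition, 0.00989 for lysosome, 0.000193 for leukocyte, 0.00251 for mural, 0.00164 for histone and 0.103 for shear stress lists. With the header names over the last 8 value columns they were 0.455 for transition, 0.0843 for lysosome, 0.000783 for leukocyte, 0.358 for mural and 0.132 for nuclear oxidative phosphorylation lists. The cause of these reversals was not tested. With the covariate the 6 libraries stayed the same and only the model changed. Where the p value is not under 0.05, the list was not called in the new direction. With tamoxifen_3 alone the p values hold no spread among tamoxifen libraries.

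With the replicate number as a block, 20 genes were higher and 1 lower. The deviations of libraries with the same number correlated at 0.195, 0.036 and 0.345 across genes, the last being the highest of all pairs. However, tamoxifen_2 correlated best with no_tamoxifen_1 (0.329). With 3 libraries per group this does not decide whether the numbers pair the samples. Depth limits low genes most, since 1 read is worth 0.7014 to 1.0803 normalised reads in the 6 libraries.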

Other observations

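Myeloid transcripts were abundant in these endothelial sorts. Mpo, the peroxidase of neutrophil granules, had 34557 to 59463 normalised reads in the 6 libraries and ranked 6 among all genes by mean. The granule protease genes Elane and Prtn3 had 4815 to 8660 and 5418 to 10479 reads. The macrophage receptor gene Csf1r had 7464 to 12229 reads, above the endothelial cadherin gene Cdh5 at 1978 to 5201 and the vascular receptor gene Kdr at 1253 to 3935. In column 6 Mpo had 61 reads and Csf1r 151, while the collagen gene Col1a1 had 233293 against 896 to 42746 in the 6 libraries. Mpo, Elane, Prtn3 and Col1a1 were singled out after their values were seen.

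A list of heat shock factor targets was written after the most changed genes had been seen, so its count is not independent evidence. Of 31 tested members 29 were positive, 5 rose over all genes and 20 rose adjusted over the list alone, with a median log2 fold change of 0.62. The camera p was 2.71e-29 with the preset correlation and 0.0125 with an estimated correlation. The cytosolic chaperone genes Hsp90aa1 (1.02 ± 0.19, SE) and Dnaja4 (2.19 ± 0.46) passed over the list alone, as did the mitochondrial chaperonin genes Hspd1 (0.55 ± 0.15) and Hspe1 (0.58 ± 0.15). Hsp90ab1 was at 0.24 ± 0.14 and Hsf1 itself at 0.17 ± 0.13, neither past it. With the mesenchymal score as a covariate 18 members passed over the list alone.

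Wdr95 ends 2393 bases from the 3' end of Hsph1, on the opposite strand. The hypothesis, formed and tested after these values were seen, was that transcription running past the 3' ends of induced heat shock genes may supply reads to genes behind them. Within 10 kb of the 20 heat shock genes past the list-alone threshold, 6 tested genes lay after a 3' end and 6 before a 5' end, with Lsm2 in both sets. Their medians were 0.37 and 0.01, a difference of 0.36 (permutation p = 0.24, two-sided). The difference passed a bound of 0.2 that was chosen after part of these values had been seen, and Wdr95, which prompted the test, is in the set. With this p the test does not decide. Wdr95 (3.31) and 1700001K19Rik (1.89), behind Hsp90aa1, were the 2 large values, while Plk4 and Coq10b were at -0.08 and 0.09.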
